A study of Mus musculus with 12 samples.

How the data were processed

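Small RNA was sequenced from the livers of 12 male mice of the C57BL/6 strain at postnatal day 84, which the labels also give as 12 weeks. Per the labels' protocols, 35 dams received either a control chow with 7% simple carbohydrates and 3% lipids or an obesogenic diet with 10% simple carbohydrates and 20% lipids plus sweetened condensed milk. Litters were brought to 6 pups on postnatal day 3, and sons were weaned on day 21 onto either diet and killed in a fasted state. The 4 groups were CC (mother and son on control diet), CO (control mother, obesogenic-fed son), OC (obesogenic mother, control-fed son) and OO (both on obesogenic diet), with 3 libraries each. Each library's table column was taken from the column number in its sample description. Replicate numbers were given in accession order and pair nothing. The labels do not name the mother or litter of each son, so sons of 1 litter could be present. The titles of OC replicate 2 and OO replicate 3 share a stem that no other title has, and the labels do not say what the stem stands for. The p-values measure the spread between these 12 libraries. Title prefixes of the samples split fully with maternal diet, and all libraries came from 1 sequencing pool with 1 index each, so no batch could be separated from maternal diet. All titles of control-fed sons end in the letter A, as does that of OO replicate 2. Those of the other obesogenic-fed sons end in C, D or E. The labels do not say what the letter stands for. A factor behind it could not be fully separated from the sons' diet.

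Per the labels' protocols, total RNA was extracted with miRNeasy columns and libraries were made with the TruSeq small RNA kit. Bowtie 1.2.3 is named in the submitters' processing notes. The genome build, the miRNA reference, the rule for reads that match several miRNAs and the filter that left the listed miRNAs are not given in the sources used here. The authors deposited 1 table of CPM, read counts scaled to a fixed total per library, for 386 mature miRNA rows, with no value at 0. In each column, 100% of the values were whole multiples of 1 step, within a tolerance of 0.001 reads. The CPM total divided by that step gave the depth that the values were scaled to, from 5.45 to 22.2 M reads per library with a median of 13.2 M reads. Columns summed to between 0.866% and 1.17% above the CPM total. Reads counted for more than 1 miRNA, or a scaling total other than the summed reads, would give such an excess, and neither was tested. Being this close to the reads of the listed miRNAs, depth here does not stand for all reads sequenced, which are not known. Of the rows, 125 had a mean under 10 CPM, 4 named several miRNAs and 6 formed 3 pairs with identical values in every library. The lowest value in the table stood for 1 read, and M reads stands for mega-reads.

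The analysis planned before the data were examined named a count model for raw counts and limma for a normalised unit. Because the table holds CPM, no count model such as edgeR or DESeq2 was used, and the DESeq2 alternative was not run. The main test was limma 3.58.1 in R 4.3.3 on log2(CPM + 1) of all 386 rows at the deposited scaling, with a mean-variance trend, 1 mean per group over the 12 libraries and 8 contrasts, two-sided. Benjamini-Hochberg adjustment was made within each contrast, and an adjusted p under 0.05 passed. A log2 change on this scale understates the change of miRNAs at low CPM. The planned filter on low values, at 0.758 CPM, removed 0 rows. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

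The miRNAs named were fixed by a rule before the data were examined: those that passed, the smallest unadjusted p up to 10 in all per contrast, the passing and up to 4 most abundant members of each list, the 5 most abundant miRNAs, and miR-122-5p, miR-451a, miR-582-3p and miR-582-5p. The last of these was not among the measured miRNAs. miR-582-3p is also in the list recalled from published work, described below, so it may have been picked from these same samples. The part of the rule on abundant list members was carried out below for the cholesterol and fatty acid metabolism list only. miRNAs outside this rule, named as calls of an alternative, were chosen after their values were seen. Of 15 fixed lists, 13 had at least 3 measured members: hepatocyte-enriched, cholesterol and fatty acid metabolism, insulin signalling and glucose metabolism, let-7 family, inflammation and steatohepatitis, stellate cell and fibrosis, biliary and other epithelium, erythroid, leukocyte, muscle with pancreas and nervous tissue, the Dlk1-Dio3 imprinted cluster, the miR-17-92 family clusters, and miRNAs recalled from published work on maternal obesity and offspring liver. The last list may hold miRNAs picked from these same samples and is not independent evidence. The endothelial list had 2 measured members and the Igf2-H19 list 0, so neither was tested. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 104 tests, beside camera with an estimated correlation and fry. Shares of the summed values and depth were compared by exact two-sided permutation within the strata of the other diet, with 400 arrangements and a smallest p of 0.005. By an exact permutation test, a comparison of 3 libraries with 3 could not go below p = 0.1.

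Alternatives were median-of-ratios factors, a filter at 10 CPM in 3 libraries, limma-voom on reads recovered from the steps, a fit of only the 6 libraries compared, an additive model, and leaving out each library. Trimmed-mean (TMM) factors, pseudocounts of 0.25 and 5, sample quality weights and log2 depth as a covariate were chosen after the data were seen. The limma fit was tested on 20 simulations of 386 miRNAs with independent noise. In each, 60 miRNAs were changed, 20 each by 0.5, 1 and 2 on the log2 scale. For the offspring-diet average it recovered 56.0% of miRNAs changed by 0.5 on the log2 scale and 89.3% of those changed by 1, with 5.03% of calls false. For CO against CC it recovered 32.3% and 75.3%. With that many changes the adjusted threshold is looser than in a contrast with few calls. The rates therefore overstate the recovery for the contrasts here. Hairpin positions came from GENCODE vM21 on GRCm38 and describe that annotation alone, since the authors' build is not given in the sources used here.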

Results

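Mature miRNAs were measured in the livers of adult male mice whose mothers and who themselves had received a control or an obesogenic diet, in a design that crossed both diets. Each of the 4 groups had 3 libraries, and 386 miRNA rows were listed. Depth was 9.94 ± 3.02 M reads in CC, 11.2 ± 5.04 in CO, 18.8 ± 2.97 in OC and 14.7 ± 6.00 in OO (SD, n = 3 each). The shallowest library was CO replicate 3, at 5.45 M reads, and the deepest OC replicate 1, at 22.2 M reads.

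The libraries were dominated by miR-192-5p, a miRNA abundant in liver and gut epithelium, which held 24.4% of the mean summed values. It was followed by miR-22-3p (17.3%), miR-148a-3p (8.30%), miR-21a-5p (4.88%) and miR-30a-5p (4.20%), while miR-122-5p, the miRNA best known as hepatocyte-specific, held 2.32%. Shares of sequenced reads need not rank miRNAs by their amount in the tissue, which was not measured here. The share of miR-192-5p was 25.4 ± 1.93% in obesogenic-fed and 23.4 ± 0.778% in control-fed sons (SD, n = 6 each, exact permutation p = 0.01, adjusted p = 0.10 over 10 tests). In CO replicate 3 it reached 29.2%, and without that library the difference went from 2.07 to 1.29 percentage points. The share of miR-122-5p was 2.23 ± 0.325% against 2.41 ± 0.128% (exact permutation adjusted p = 0.54), a difference of -0.179 percentage points that was -0.102 without CO replicate 1 and -0.297 without CO replicate 3. The erythroid list held 0.486 ± 0.212% in obesogenic-fed and 0.384 ± 0.0874% in control-fed sons, and the let-7 list 5.86 ± 0.989% and 5.32 ± 0.845% (exact permutation adjusted p = 0.58 for both). Without CO replicate 1 the erythroid difference went from 0.101 to 0.0294 percentage points. The let-7 difference went from 0.534 to 0.142 percentage points without CO replicate 3, to 0.276 without CC replicate 1 and to 0.802 without CO replicate 1. Depth averaged 16.7 ± 4.80 M reads with obesogenic and 10.6 ± 3.78 M reads with control mothers (SD, n = 6 each, exact permutation p = 0.05, adjusted p = 0.25).

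**Figure D1:**
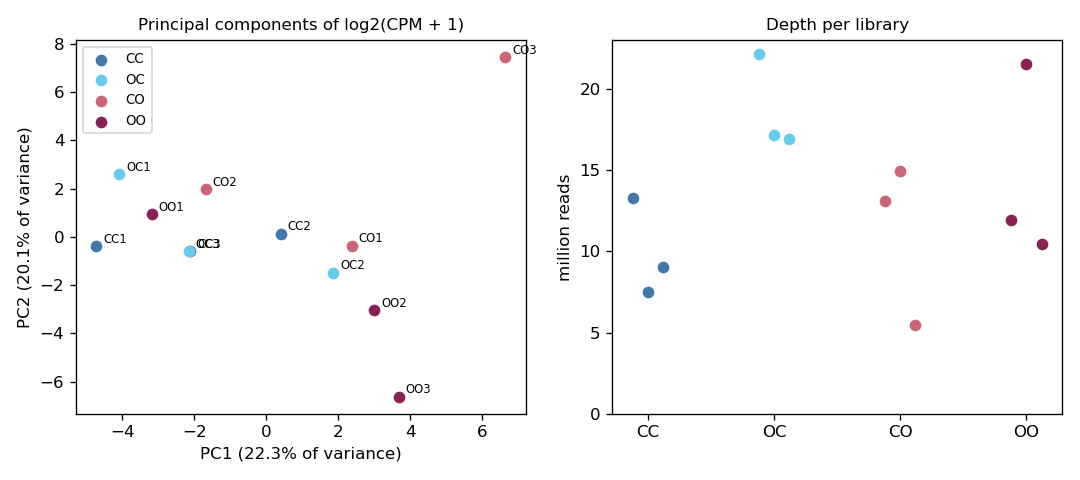
Left, the 12 libraries on the first 2 principal components of log2(CPM + 1), which held 22.3% and 20.1% of the variance, with CO replicate 3 at the upper right and CC replicate 3 under OC replicate 3. Right, depth per library by group, from 5.45 to 22.2 M reads.

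The effect of the sons' own diet was first taken as the average over both maternal diets, with 6 libraries against 6. In obesogenic-fed sons miR-5099, miR-182-5p and miR-31-5p fell, and no miRNA rose past the test. On the log2 scale miR-5099 fell by 1.14 (SE 0.104), from 491 ± 73.4 CPM in control-fed to 222 ± 27.7 CPM in obesogenic-fed sons (SD, n = 6 each). miR-182-5p, which is encoded in 1 cluster with miR-183 and miR-96 and known from lipid and sensory-organ studies, fell by 0.98 (SE 0.153), from 2043 ± 468 to 1034 ± 232 CPM. miR-31-5p, a miRNA studied in epithelia and inflammation, fell by 0.43 (SE 0.0692), from 595 ± 37.6 to 442 ± 20.2 CPM. For each of the 3, all 6 obesogenic-fed libraries lay below all 6 control-fed ones. The libraries separated fully, in either direction, for 10 of 386 miRNAs (2.59%). Since the 3 were picked by their p in these libraries, the separation is no independent evidence.

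**Figure D2:**
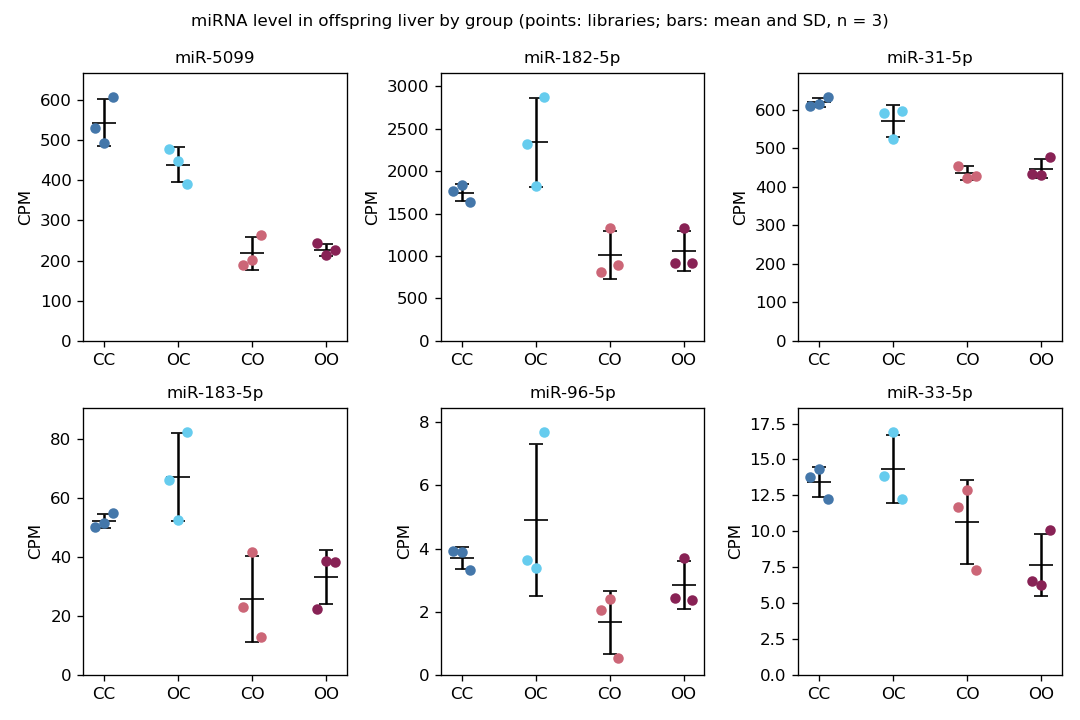
CPM of 6 miRNAs per library in the 4 groups, with points for libraries and bars for the mean and SD (n = 3). All 6 libraries of obesogenic-fed sons lay below those of control-fed sons for miR-5099 (188 to 264 against 391 to 606 CPM), miR-182-5p (809 to 1330 against 1638 to 2872 CPM) and miR-31-5p (423 to 476 against 524 to 632 CPM), while miR-96-5p and miR-33-5p overlapped.

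By limma with Benjamini-Hochberg adjustment, these 3 of 386 miRNAs passed (adjusted p = 8.23e-05 for miR-5099 and 0.0074 for the other two), and 57 had an unadjusted p under 0.05 where chance gives 19.3. The 3 passed under every alternative run, whereas the count reached 8 with median-of-ratios factors, 2 higher and 6 lower, and 7 with TMM factors, 2 higher and 5 lower, with miR-183-5p, let-7c-1-3p, miR-1933-3p and miR-378a-3p added under both. Without OC replicate 2 the count was 5, with miR-1247-5p and miR-150-5p added, and with sample quality weights 12. Missing the threshold at the deposited scaling were miR-183-5p (log2 change -1.07, SE 0.247, adjusted p = 0.073), let-7c-1-3p (-0.47, adjusted p = 0.073), miR-1933-3p (0.49, adjusted p = 0.073), miR-378a-3p (0.30, adjusted p = 0.0765), miR-1247-5p (-0.86, adjusted p = 0.0765), miR-184-3p (-0.81, adjusted p = 0.13) and miR-33-5p (-0.59, adjusted p = 0.13). miR-378a-3p, whose hairpin lies in an intron of the mitochondrial co-activator gene Ppargc1b, stood at 15208 ± 1406 CPM in obesogenic-fed and 12312 ± 621 CPM in control-fed sons. miR-33-5p, encoded in an intron of the sterol regulator gene Srebf2, stood at 9.14 ± 2.82 and 13.9 ± 1.72 CPM.

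In GENCODE vM21 on GRCm38, the miR-5099 hairpin lies on chromosome 12 at 36816205 to 36816278, plus strand, outside other annotated genes. The miR-182 hairpin lies on chromosome 6 at 30165918 to 30165992, minus strand, with those of miR-96 (30169446 to 30169551) and miR-183 (30169668 to 30169737) on the same strand, all outside other genes. The miR-31 hairpin lies on chromosome 4 at 88910557 to 88910662, minus strand, in an exon of the long noncoding RNA gene AL805899.1. No stretch of 18 bases of the miR-5099 or miR-182 hairpin occurred in the annotated transcripts of another gene. That search covered annotated transcripts only, so reads of miR-5099 from unannotated RNA were not addressed.

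Among the fixed lists, cholesterol and fatty acid metabolism had 19 measured members, of which 1 (miR-182-5p) fell and 18 did not pass over all miRNAs. Adjusted over the list alone, 5 passed: miR-182-5p, miR-183-5p, miR-33-5p and miR-96-5p with lower and miR-378a-3p with higher values. Its most abundant members, miR-148a-3p (log2 change 0.03), miR-27b-3p (0.09) and miR-122-5p (-0.12), did not pass. The list was not called in either direction (camera adjusted p = 0.88, and 0.99 with an estimated correlation), with 10 members higher and 9 lower, a median of 0.03 and a mean of -0.13. In fry's mixed test of change in either direction its adjusted p was 0.0018. Fry does not compare a list with the other miRNAs, so a small mixed p can rest on members already called. It is no separate evidence of a change of the list. The inflammation and steatohepatitis list had 13 members, of which miR-31-5p fell and 12 did not pass (1 adjusted over the list alone, camera adjusted p = 0.76, fry mixed adjusted p = 0.0019). In the other 11 lists tested, 0 members passed by limma over all miRNAs and 0 adjusted over the list alone, and no list passed camera. Camera adjusted p was 0.66 for the hepatocyte-enriched list (13 members), 0.83 for insulin signalling and glucose metabolism (16), 0.55 for the let-7 family (9), 0.45 for stellate cell and fibrosis (13) and 0.61 for biliary and other epithelium (7). It was 0.61 for the erythroid list (5), 0.89 for leukocyte (8), 0.99 for muscle with pancreas and nervous tissue (8), 0.93 for the Dlk1-Dio3 cluster (15), 0.55 for the miR-17-92 family clusters (10) and 0.88 for the list from published work (13), which is recalled and not independent evidence. The sign of the mean differed from the direction of the camera test for the Dlk1-Dio3 cluster (mean -0.01, direction up), the muscle, pancreas and nervous tissue list (-0.21, up) and the list from published work (mean 0.04, median -0.07, direction down). Without CC replicate 1 the stellate cell list passed, at a camera adjusted p of 0.041.

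In sons of control-fed mothers, 3 libraries of CO were set against 3 of CC. On the log2 scale miR-5099 fell by 1.32 (SE 0.147) in obesogenic-fed sons, from 543 ± 58.1 to 218 ± 40.3 CPM (SD, n = 3 each). miR-31-5p fell by 0.51 (SE 0.0979), from 619 ± 11.6 to 436 ± 17.1 CPM, and let-7c-1-3p fell by 0.77 (SE 0.149), from 2.99 ± 0.315 to 1.34 ± 0.10 CPM. let-7c-1-3p, the minor arm of a let-7 hairpin, was among the least abundant miRNAs. Its log2 change depended on the pseudocount, at -1.03 with 0.25 and -0.33 with 5. miR-182-5p stood at 1747 ± 99.8 and 1012 ± 279 CPM (log2 change -0.82, adjusted p = 0.17 by limma). By limma with Benjamini-Hochberg adjustment, 3 of 386 passed, all lower (adjusted p = 5.98e-04, 0.035 and 0.035), with 63 at an unadjusted p under 0.05, 12 higher and 51 lower. The median log2 change over all miRNAs was -0.05 here, 0.02 with median-of-ratios and 0.06 with TMM factors. In CO replicate 3 the median deviation from the mean of all libraries was -0.20 on the log2 scale. The excess of lower values was therefore not separated from the scaling. Calls for miR-31-5p and let-7c-1-3p were lost on leaving out any 1 of 11 libraries, the exception being OO replicate 3, with limma adjusted p up to 0.25 for both. Without CO replicate 2 the count was 4, miR-5099 with miR-182-5p, miR-183-5p and miR-3084-3p. Both calls were also lost in the fit of the 6 libraries alone (limma adjusted p = 0.181 for both) and with TMM factors (0.109 for miR-31-5p and 0.0624 for let-7c-1-3p), where only miR-5099 passed. With median-of-ratios factors miR-31-5p was lost (limma adjusted p = 0.0846), with limma-voom let-7c-1-3p was (0.0543), and the stricter filter left let-7c-1-3p out of the test. With log2 depth as a covariate 10 miRNAs passed. Adjusted over the list alone, 3 members of the cholesterol and 1 of the inflammation list passed.

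In sons of obesogenic-fed mothers, 3 libraries of OO were set against 3 of OC. miR-182-5p fell by 1.15 on the log2 scale (SE 0.217, from 2340 ± 524 to 1056 ± 236 CPM) and miR-5099 fell by 0.95 (SE 0.147, from 439 ± 44.0 to 227 ± 14.9 CPM; SD, n = 3 each). miR-31-5p stood at 571 ± 40.7 and 447 ± 25.2 CPM (log2 change -0.35, adjusted p = 0.31 by limma), and miR-33-5p at 14.3 ± 2.38 and 7.64 ± 2.15 CPM (-0.84, adjusted p = 0.30 by limma). By limma with Benjamini-Hochberg adjustment 2 of 386 passed, both lower (adjusted p = 0.016 for miR-5099 and 0.0435 for miR-182-5p), with 28 at an unadjusted p under 0.05. No miRNA passed on leaving out OC replicate 1, OC replicate 2, or any of the 3 OO libraries (limma adjusted p for miR-5099 between 0.052 and 0.112). Without CC replicate 1, 2 or 3, CO replicate 3 or OC replicate 3, only miR-5099 passed, as in the fit of the 6 libraries alone and with log2 depth as a covariate (limma adjusted p for miR-182-5p of 0.181 and 0.116). Adjusted over the list alone, 2 members of the cholesterol list passed (fry mixed adjusted p = 0.032). Across both maternal diets the log2 changes of all miRNAs correlated at r = 0.23 between the strata, which is a correlation across miRNAs that are not independent replicates.

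For the effect of maternal diet, averaged over the sons' diet, miR-326-3p had the smallest p, at 45.1 ± 5.90 CPM with obesogenic and 29.6 ± 4.75 CPM with control mothers (log2 change 0.60, SE 0.122, adjusted p = 0.17 by limma; SD, n = 6 each). miR-335-3p (0.56, adjusted p = 0.26) and miR-3084-3p (0.55, adjusted p = 0.27) followed, also by limma. The erythroid list, of miRNAs abundant in red cells such as miR-451a and miR-144-3p, lay lower (all 5 members, mean log2 change -0.26, camera adjusted p = 0.015), which became adjusted p = 0.99 with an estimated correlation. That list missed the threshold with median-of-ratios (0.094) and TMM factors (0.11), and without CO replicate 1 (0.32), OC replicate 1 (0.18), OO replicate 2 (0.075) or CC replicate 2 (0.053), all by camera. Its mean was -0.087 without CO replicate 1 and -0.15 without OC replicate 1. By limma with Benjamini-Hochberg adjustment 0 of 386 miRNAs passed, 27 had an unadjusted p under 0.05, and limma-voom also gave 0. Adjusted over the list alone, 1 member of the cholesterol list passed. The 95% interval excluded a log2 change of 1 in either direction for 368 miRNAs.

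In control-fed sons, OC against CC, 0 miRNAs passed by limma, with 4 at an unadjusted p under 0.05, fewer than the 19.3 that chance gives, and 0 by limma-voom. The smallest p belonged to miR-222-5p (log2 change -0.65, SE 0.240) and miR-1933-3p (-0.40, SE 0.160), both with a limma adjusted p of 0.9999. In obesogenic-fed sons, OO against CO, 0 passed by limma and 0 by limma-voom, with 47 at an unadjusted p under 0.05, 38 higher and 9 lower. The median log2 change over all miRNAs was 0.13 here and 0.02 with median-of-ratios factors. miR-326-3p stood at 49.2 ± 3.81 CPM in OO and 27.6 ± 6.64 CPM in CO (log2 change 0.84, SE 0.173, or 0.70 above the median of all miRNAs), and miR-335-3p had a log2 change of 0.80 (both limma adjusted p = 0.17). Without CO replicate 2, miR-3084-3p and miR-335-5p passed, each at a limma adjusted p of 0.0497. Adjusted over the list alone, 2 members of the cholesterol list and 1 of the list from published work passed. The erythroid list lay lower in OO than in CO (5 of 5 members, mean log2 change -0.56, camera adjusted p = 0.0022), as did the Dlk1-Dio3 imprinted cluster (9 of 15 members, mean -0.18, camera adjusted p = 0.0059). Both had an adjusted p of 0.99 with an estimated correlation. Without CO replicate 1 the erythroid list stood at a mean of -0.22 and a camera adjusted p of 0.21, and the Dlk1-Dio3 list at an adjusted p of 0.097. The Dlk1-Dio3 mean was -0.084 without OO replicate 3 (camera adjusted p = 0.31), -0.083 without CO replicate 2 (0.030), -0.32 without CO replicate 3 (5.93e-04) and -0.29 without OO replicate 1 (5.63e-05).

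With both diets together, OO against CC, miR-5099 fell by 1.25 on the log2 scale (SE 0.147, n = 3 each, limma adjusted p = 0.0011), the only 1 of 386 to pass, with 47 at an unadjusted p under 0.05. miR-31-5p (log2 change -0.47, limma adjusted p = 0.096) missed the threshold and passed with median-of-ratios and TMM factors. miR-582-3p, whose hairpin lies in an intron of the phosphodiesterase gene Pde4d on chromosome 13 at 109324744 to 109324824, stood at 11.4, 31.2 and 98.4 CPM in the 3 OO libraries and at 6.83 to 9.51 CPM in CC. Its log2 change was 1.95 (SE 0.595, limma adjusted p = 0.24), and among the alternatives it passed only without OO replicate 1 (2.68, adjusted p = 0.0368). Without OO replicate 3 its log2 change was 1.18 (limma adjusted p = 0.547), and these were the lowest and highest values over its alternatives. Without CO replicate 3 the count was 3, with miR-31-5p and miR-326-3p, and without CC replicate 1 it was 2, with miR-3068-5p. Adjusted over the list alone, 3 members of the cholesterol and 1 of the inflammation list passed. In the other contrasts miR-582-3p ranged from 0.45 to 1.5, with no limma adjusted p under 0.24. It belongs to the recalled list, so its values are not independent evidence. The log2 changes of miR-122-5p lay between -0.24 and -0.04 and those of miR-451a between -0.54 and 0.46 over the 8 contrasts, and none passed by limma.

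Whether the sons' diet acted differently by maternal diet was tested by the interaction. The smallest p belonged to miR-335-5p (difference of log2 changes 0.78, SE 0.234) and miR-330-3p (0.85, SE 0.286), both with a limma adjusted p of 0.77. By limma 0 of 386 passed, with 15 at an unadjusted p under 0.05, and 0 by limma-voom. With log2 depth as a covariate miR-126-5p, an endothelial miRNA, passed. The median over all miRNAs was 0.13, and 0.01 with median-of-ratios factors. Intervals were wide, excluding a difference of 1 on the log2 scale for 245 miRNAs. Of the 104 list tests over all contrasts, 6 passed camera and 0 passed with an estimated correlation or in fry's directional test. Further lists passed camera in some fits with 1 library left out. Among them, the adjusted p ranged from 0.0038 to 0.74 for the let-7 list in CO against CC. For the Dlk1-Dio3 list it ranged from 0.0013 to 0.85 in OC against CC and from 0.0028 to 0.85 in OO against OC.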

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

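For 3 miRNA lists the interaction of maternal and offspring diet passed limma's camera with a preset correlation. Each had an adjusted p of 0.987 with an estimated correlation and 0.996 in fry's directional test, and fry's mixed test gave 0.785 for the Dlk1-Dio3 list, 0.918 for the erythroid and 0.946 for the let-7 list, so a difference between maternal diets was not shown. With the preset correlation the Dlk1-Dio3 imprinted cluster had an adjusted p of 0.0022, with 11 of 15 members negative and a mean of -0.29. The erythroid list had 0.0063, with 5 of 5 members negative and a mean of -0.60. The let-7 family had 0.013, with 9 of 9 members negative and a mean of -0.22. In each list 0 members passed by limma, over all miRNAs or adjusted over the list alone.

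Leaving out single libraries ended each of these calls. The Dlk1-Dio3 list stood at a camera adjusted p of 0.14 without OO replicate 3 (mean -0.19) and 0.053 without CC replicate 2 (mean -0.18), and its mean was -0.19 without CO replicate 2, where the call held (0.0087). The erythroid list stood at 0.23 without CO replicate 1 (mean -0.26), 0.12 without OC replicate 2 (mean -0.39) and 0.087 without CC replicate 3. The let-7 list stood at 0.57 without CO replicate 3 (mean -0.099), 0.21 without OC replicate 1 (mean -0.057), 0.082 without OO replicate 1 (mean -0.14), 0.064 without CC replicate 1 (mean -0.14) and 0.053 without OO replicate 3. Without CO replicate 1 its mean was -0.35, where the call held (6.82e-04). No biological explanation was tested.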

How the results depend on the processing

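Trimmed-mean (TMM) factors, pseudocounts of 0.25 and 5, sample quality weights and log2 depth as a covariate were chosen after the data were seen. miR-5099, miR-182-5p and miR-31-5p passed in the offspring average under each of the 21 alternatives run, with limma adjusted p up to 0.00154, 0.0341 and 0.0416. For the log2 changes of the miRNAs named, 2844 values kept direction and side of the threshold, 45 lost the threshold, 38 gained it and 67 turned sign. Most of the 145 results behind these values missed the threshold in the main fit and could not lose it. Only the 3 calls in CO against CC, 2 in OO against OC, 1 in OO against CC and 3 in the offspring average could. The cause of the losses, gains and turns of sign was not tested, except that fits of 6 libraries or with 1 left out hold fewer samples. Library totals alone and no filter gave the values reported, since the planned filter removed 0 miRNAs, and the stricter filter left 274. The DESeq2 alternative was not run, since the table holds CPM, for which the plan named limma. Reads recovered from the steps were used for limma-voom only. The shallowest library, CO replicate 3, had the lowest quality weight, 0.161 against a highest of 2.16. No paired analysis was possible because the labels give no replicate numbers.

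Counts of passing miRNAs moved as follows. For CO against CC the count of 3 became 1 with the 6 libraries alone, 1 with TMM factors, 2 with median-of-ratios factors, 2 with limma-voom, 2 with the stricter filter, which left out let-7c-1-3p, and 10 with depth as a covariate, and 1 to 4 with 1 library left out. For OO against OC the count of 2 became 1 with the 6 libraries alone and 1 with depth, miR-5099 in both, and 4 with quality weights, and 0 to 2 with 1 library left out. For OO against CC the count of 1 became 2 with median-of-ratios factors, 2 with TMM factors, 4 with quality weights and 2 with depth, and 1 to 3 with 1 library left out. The maternal average went from 0 to 1 with quality weights (miR-326-3p) and 1 with depth (miR-3061-3p). The offspring average went from 3 to 8 with median-of-ratios factors, 7 with TMM factors and 12 with quality weights, and 3 to 5 with 1 library left out. The interaction went from 0 to 1 with depth, and OO against CO from 0 to between 0 and 2 with 1 library left out.

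All 6 list tests that passed camera had an adjusted p of 0.987 with an estimated correlation and 0.996 in fry's directional test. In fry's mixed test the Dlk1-Dio3 list had 0.583 in OO against CO and 0.785 in the interaction, the erythroid list 0.785, 0.952 in the maternal average and 0.918 in the interaction, and the let-7 list 0.946. The erythroid list in the maternal average had 0.0940 with median-of-ratios and 0.106 with TMM factors. In the offspring average, fry's mixed test gave 0.00179 for the cholesterol and 0.00186 for the inflammation list. The direction turned there with median-of-ratios and TMM factors for the Dlk1-Dio3 list (0.943 and 0.948) and the insulin list (0.750 and 0.752).

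With 1 library left out, camera's adjusted p for the Dlk1-Dio3 list ranged from 1.33e-06 to 0.140 in the interaction, 5.63e-05 to 0.307 in OO against CO and 0.588 to 0.992 in the offspring average. For the erythroid list it ranged from 7.45e-05 to 0.235 in the interaction, 0.00108 to 0.323 in the maternal average, 4.79e-04 to 0.212 in OO against CO and 0.256 to 0.979 in the offspring average. For the let-7 list it ranged from 6.82e-04 to 0.571 in the interaction and 0.104 to 0.974 in the offspring average. In the offspring average it ranged from 0.575 to 0.933 for inflammation, 0.612 to 0.948 for insulin, 0.803 to 0.975 for the list from published work, 0.692 to 0.992 for muscle, pancreas and nervous tissue and 0.0410 to 0.782 for the stellate cell list. The maternal-diet difference in share ranged from -0.237 to 0.422 percentage points for the let-7 list and from -1.22 to 0.155 for miR-192-5p.

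With TMM factors the sign turned for miR-192-5p in OC against CC (-0.0033), miR-30a-5p in OO against CO (-0.031), miR-30a-5p in CO against CC (0.012), miR-122-5p in CO against CC (0.083), miR-30a-5p in OO against OC (-0.014), miR-30a-5p in OO against CC (-0.019), miR-451a in OO against CC (-0.0025), miR-30a-5p in the maternal average (-0.018), miR-148a-3p in the interaction (-0.11), miR-30a-5p in the interaction (-0.026). With log2 depth as a covariate the sign turned for miR-22-3p in OC against CC (-0.12), miR-122-5p in OC against CC (0.10), miR-451a in OC against CC (-0.28), miR-451a in OO against OC (0.093), miR-30a-5p in OO against CC (-0.015), miR-451a in OO against CC (-0.19), miR-192-5p in the maternal average (0.049). With median-of-ratios factors the sign turned for miR-192-5p in OC against CC (-0.0089), miR-30a-5p in OO against CO (-0.0086), miR-122-5p in CO against CC (0.036), miR-30a-5p in OO against OC (-0.033), miR-30a-5p in OO against CC (-0.043), miR-451a in OO against CC (-0.027), miR-30a-5p in the maternal average (-0.0095), miR-148a-3p in the interaction (-0.081). With sample quality weights the sign turned for miR-30a-5p in OC against CC (0.0051), miR-21a-5p in OO against OC (0.10), miR-451a in OO against CC (-0.038), miR-192-5p in the maternal average (0.0046), miR-22-3p in the interaction (-0.020). When 1 library at a time was left out, signs turned within the following ranges of the log2 change. For CO against CC, miR-122-5p ranged from -0.18 to 0.048, miR-148a-3p ranged from -0.056 to 0.10. For OC against CC, miR-122-5p ranged from -0.083 to 0.017, miR-192-5p ranged from -0.025 to 0.042, miR-21a-5p ranged from -0.25 to 0.016, miR-22-3p ranged from -0.015 to 0.030, miR-30a-5p ranged from -0.011 to 0.019, miR-451a ranged from -0.074 to 0.27. For OO against CC, miR-21a-5p ranged from -0.29 to 0.030, miR-30a-5p ranged from -0.060 to 0.084, miR-451a ranged from -0.15 to 0.19. For OO against CO, miR-192-5p ranged from -0.13 to 0.016. For OO against OC, miR-148a-3p ranged from -0.015 to 0.12, miR-21a-5p ranged from -0.21 to 0.12, miR-30a-5p ranged from -0.060 to 0.084, miR-451a ranged from -0.22 to 0.10. For the interaction, miR-148a-3p ranged from -0.041 to 0.11, miR-192-5p ranged from -0.14 to 0.015, miR-582-3p ranged from -0.051 to 1.45. For the maternal average, miR-192-5p ranged from -0.067 to 0.0082, miR-451a ranged from -0.37 to 0.035. For the offspring average, miR-148a-3p ranged from -0.0023 to 0.074, miR-21a-5p ranged from -0.023 to 0.14, miR-451a ranged from -0.010 to 0.40.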

Other observations

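Depth as a covariate was an alternative chosen after the data were seen. The test of the cluster of miR-182, miR-183 and miR-96 was chosen after the result for miR-183-5p had been seen, the test of epithelial cells against miR-182-5p after that against miR-31-5p, and the spread over repeated thinnings, the spread between libraries and the median correction for CO replicate 3 were added after a first result. Other tests below were set down before their result was seen, though after the calls themselves.

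Lower miR-5099, miR-182-5p and miR-31-5p in obesogenic-fed sons were set against technical explanations. With log2 depth of the libraries, the total that their values were scaled to, as a covariate, 3 of the 3 kept a 95% interval below 0. With median-of-ratios factors, which address a few miRNAs taking most of the reads, 3 of the 3 did too. Those factors moved the median log2 change of all miRNAs only from -0.016 to 0.0016. Leaving out each of the 12 libraries, the highest upper bound was -0.24, so no single library carried the 3 changes. All of these are fits reported above, under which the 3 miRNAs passed. Intervals below 0 follow from that and are no further evidence. Of 100 splits of the libraries within maternal diet, drawn from 200 and with the real split included, 2 gave at least 3 passing miRNAs. The real split gave 3, and so did the highest other. The share of such splits lay under 0.05, but it was not adjusted for the other comparisons split in the same way. It also takes the libraries as exchangeable, which sons of the same litter would not be. Chance was therefore not excluded. An effect of the sons' diet stays open as a hypothesis found and examined on the same data, and reads of miR-5099 from unannotated RNA were not tested. A factor behind the last letter of the titles, which nearly follows the sons' diet, was not tested either.

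A smaller share of biliary or other epithelial cells was weighed for lower miR-182-5p and miR-31-5p with the mean of 5 miR-200-family miRNAs, which had a log2 change of 0.23 (SE 0.306) with the sons' diet. That change lay 1.21 above that of miR-182-5p, with a lower 95% bound of 0.56 (0.41 at the lowest with 1 library left out), which argues against a loss of cells bearing this family as the whole cause of lower miR-182-5p. For miR-31-5p it stays a candidate explanation, since the family's own lower 95% bound of -0.48 reached past the miR-31-5p change of -0.43. No difference per library was tested for miR-31-5p, so it was not weighed in the same way as miR-182-5p. Lower output of the whole transcript of miR-182, miR-183 and miR-96 is a further hypothesis: 2 of the 2 other members, miR-183-5p and miR-96-5p, had a 95% interval below 0, although neither passed limma's adjusted threshold (adjusted p = 0.073 and 0.17). A joint variation of miR-182-5p and miR-33-5p, both known from cholesterol metabolism, was not seen within groups. Their deviations from group means correlated at r = -0.15 over 12 libraries (permutation p = 0.72 from 100000 resamples, Spearman's rho = -0.21, permutation p = 0.61, 1 relation tested), and at -0.36 without the 2 libraries farthest from the median. Such deviations leave out the diet effect, so they cannot decide on a joint lowering by diet. In the offspring average the log2 changes were -0.98 for miR-182-5p and -0.59 for miR-33-5p, of which only the first passed limma.

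CO replicate 3 lay apart on the principal components, with the lowest mean correlation to other libraries (0.986) and a mean correlation distance 1.07 times the largest of the other 11. That largest was OO replicate 3 (mean correlation 0.987), at the other end of the 2nd component (-6.63 against 7.46). The median deviation of OO replicate 3 was 0.129 on the log2 scale, against -0.204 in CO replicate 3. After all were thinned to the depth of CO replicate 3, its ratio to the largest was 1.04 (SD 0.0174 over 50 thinnings). The other 11 distances had an SD of 0.109 of the largest, so lower depth stays open. A ratio above 1 had been set as the bound against depth, but this library was singled out as the farthest and the excess lay within that SD. Of red or white blood cells in the tissue, 1 of the 2 lists lay outside the range of the other 11 libraries, the leukocyte list at a mean log2 value of 5.96 against 6.26 to 6.94. Since 6 of 13 lists lay outside that range, and 6 partly different ones after each library's median shift was taken off, a lower leukocyte share may be part of a wider difference, and RNA quality was not measured here. Without this library the offspring-diet average gave 4 miRNAs, the original 3 and miR-223-3p, a miRNA of myeloid cells.

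For the other comparisons, 3 libraries against 3 make 10 splits, too few for a share under 0.05. CO against CC gave 3 miRNAs in the real split and 0 in the highest other, with 1 split as large. OO against OC gave 2 and 0, with 1 split as large. OO against CC gave 1 and 2, with 2 splits as large. OC against CC gave 0 and 1, and OO against CO gave 0 and 0. The maternal average and the interaction gave 0 in the real split and 1 in the highest other. With a real count of 0, all 10 or all 100 splits give as many by construction, so for these 4 comparisons the splits say nothing about chance.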
